A study of Oryza sativa with 8 samples.

How the data were processed

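Gene expression was measured on 8 one-colour Affymetrix rice arrays, made from total RNA of shoots and leaves of seedlings at the 4-leaf stage. Per the labels, the seedlings were wild-type Zhonghua 11 (ZH11) or carried an OsTMF overexpression construct in that cultivar (OE), and they were sampled before and after 24 h in a chamber held at 4 °C. This gave 4 groups of 2 arrays, named ZH11 normal, ZH11 cold, OE normal and OE cold. In both OE groups replicate 1 was line OE-24 and replicate 2 was line OE-29. Per the labels the ZH11 replicates were independent biological ones, so their numbers pair nothing. No array was left out, and every per-array column was used.

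The deposited values are probe-set signals in units of intensity on a linear scale, with 1 decimal. The summarisation method, the software and the normalization between arrays are not given in the sources used here. Array medians ran from 27.2 to 28.2, and the table held 0 control probe sets. Of the 57194 probe sets, 22436 were annotated with 1 gene, 95 with several genes and 34663 with none. The first class covered 17905 genes, of which 2457 had a name other than a locus number. Names came from the probe annotation and from the synonyms of the reference gene table (assembly ASM3414082v1). Probe sets of closely related genes can cross-hybridise, and how far they did so is uncertain. Where a gene had several tested probe sets, the one with the highest mean signal stood for it.

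Values were taken to log2 after adding 16, with no further scaling. Probe sets were tested when their mean over the 8 arrays lay above the 40th percentile, which left 34316 probe sets and 15841 genes. A group-means model was fitted with limma 3.58.1 (lmFit and eBayes with a trend) in R 4.3.3 with statmod 1.5.0. All 4 groups shared the estimate of the spread, with 4 residual degrees of freedom. The 7 two-sided comparisons were cold in ZH11, cold in OE, OE against ZH11 before cold, OE against ZH11 after cold, the interaction (the cold change in OE minus that in ZH11), OE against ZH11 over both treatments, and cold over both genotypes. P-values were adjusted by the Benjamini-Hochberg method over the tested probe sets, and a call needed an adjusted p under 0.05. Counts at 2-fold or more are given beside. The number of arrays limits the precision, and ± gives the standard error of a log2 change in limma.

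The replicate number was not used as a block. Over the tested probe sets, the difference between replicates 1 and 2 before cold had a correlation of 0.121 with the difference after cold in OE, and -0.02 in ZH11. Models with the replicate as a block, over all arrays or within each genotype, were alternatives.

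There were 38 gene lists. They were DREB1 factors, LEA and dehydrins, cold-associated regulators with LTI6, trehalose with proline and inositol synthesis, photosystems with Rubisco and electron transfer, chlorophyll synthesis, chlorophyll breakdown, BURP proteins with pectin methylesterase inhibitors, cellulose and xylan synthesis, cellulose synthase-like, wall loosening, class III peroxidases, lignin and phenylpropanoid, reactive oxygen scavenging, circadian clock, abscisic acid and SnRK2, PP2C phosphatases, WRKY, NAC, heat shock proteins, heat shock factors, ribosomal proteins, cell cycle with replication and histones, vesicle transport, starch and sucrose enzymes, sugar transporters, jasmonate, Aux/IAA, type A response regulators with cytokinin oxidases, aquaporins, calcium sensors with their kinases, MAP kinases, chitinases with defence proteins, diterpenoid phytoalexins, and markers of other tissues (seed storage, meristem homeobox, root, flower and meiosis). The comparisons, thresholds, alternatives and the subjects of the lists were chosen before the data were examined. The symbols that make up each list were written once the annotation was seen, because it gave symbols rather than descriptions, but before any expression comparison was made. The lists held 787 genes, 8 of them in over 1 list. Lists with at least 3 tested members were tested with camera at a correlation of 0.01 and, beside it, with an estimated correlation, adjusted over lists within a comparison. Member counts were taken over all genes tested and adjusted over the list alone.

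Named genes were chosen by rule among genes with a name, past the threshold, without overlap between the 2 groups (no such condition applies to the interaction), and with a mean signal above the median of the tested probe sets. For each cold comparison these were the 8 largest rises and 8 largest falls, and for each comparison involving genotype the 5 largest in each direction. For each list they were the 2 largest changes per direction past the threshold, of which the smallest are left out here. OsTMF itself was to be named in every array.

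The agreement between comparisons was described by Pearson's correlation across genes, which are not independent replicates. The procedure was tested on simulated data with the residual spread of these arrays. For OE against ZH11 before cold, 86% of 2-fold changes and 38% of 1.5-fold changes were recovered, with 6 false calls. For the interaction, 60% of 2-fold and 88% of 4-fold changes were recovered, with 4 false calls. Camera called the shifted list and 0 of 20 unchanged ones. The simulated probe sets were independent of each other, with the spreads shuffled over them. This does not test camera on lists with correlated members.

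The alternatives were pseudocounts of 1 and 64, quantile normalization, median centring, no filter, a filter at the 60th percentile, eBayes without a trend, only the 4 arrays of a comparison, the replicate blocks, the stricter thresholds (2-fold, or an adjusted p under 0.01), the mean of all probe sets of a gene, fry in place of camera, and leaving out each array in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3.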

Results

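The arrays compared wild-type rice with plants overexpressing OsTMF before and after a day of chilling, and so address whether the level of this gene alters the transcript response to cold. TMF proteins in other eukaryotes are coiled-coil proteins of the Golgi. Treatment was the main axis of the data. The first principal component of the tested probe sets held 87.3% of the variance and separated cold from normal arrays, and the second held 6.7% and separated OE from ZH11. Spearman correlations were 0.99 to 0.994 within groups, 0.986 to 0.993 between genotypes in the same treatment, and 0.955 to 0.962 across treatments. The median absolute log2 difference between replicates was 0.09 in both ZH11 groups, 0.10 in OE cold and 0.14 in OE normal, where the replicates are different lines. Between OE normal and ZH11 normal arrays it was 0.10 to 0.13, so before cold the genotypes were no further apart than the OE lines. On the second component OE-24 and OE-29 before cold lay at -3.3 and -19.7, and ZH11 normal at 11.2 and 13.6. The overexpressed gene was not matched to a probe set through the annotation used here (0 genes matched), so its own level is not given.

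Chilling is a broad stress for rice, a plant of warm climates. It slows growth and photosynthesis, and cells respond through calcium, hormone and DREB1 transcription factor signalling. In ZH11, cold changed 20668 of 34316 probe sets, 60.2% of those tested. Signals rose for 9021 and fell for 11647, and at 2-fold or more the counts were 2458 and 3809. The balance depended on scaling, with 10239 higher and 10756 lower after quantile normalization. Over genes, 4075 rose and 7159 fell. The normal arrays were taken before the move to the chamber, so this comparison also holds a day of growth and the change of surroundings. Among named genes the sugar transporter gene SWEET2b rose most, by 5.29 ± 0.13 on the log2 scale, from a mean signal of 136 to 5960 (adjusted p = 5.54e-10). The heat shock factor gene HSF05 followed at 4.49 ± 0.12, then RIBA2 at 4.17, CEBIP at 4.07, JAZ9 at 3.81, SAT1 at 3.76, C3H3 at 3.67 and the glutaredoxin gene GRXC15 at 3.61. The mean signals of HSF05, JAZ9, C3H3 and GRXC15 before cold were 41, 26.6, 42.3 and 50.6, low signals on these arrays, so the sizes and order of these rises depend on the pseudocount. The kinase gene CIPK10 had the largest fall, -4.82 ± 0.09, from 2620 to 77.6 (adjusted p = 2.16e-10). HOX4 changed by -3.68, the light-harvesting genes LHCP, RCABP69 and CAB2R by -3.67, -3.49 and -3.39, the aquaporin gene TIP1-2 by -3.46, and ADF-11 and CKS1 by -3.36 each. The other probe set of SAT1, dimmer, gave 0.87, and that of CAB2R gave -4.82. All of these genes kept their calls in each fit that left out 1 array.

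The 8 lists called in ZH11 pointed up, among them lists of hormone and calcium signalling. Of 26 jasmonate genes, 19 rose, 5 fell and 2 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.000125, or 0.565 with an estimated correlation). JAZ9 and JAZ11 (3.46) rose most, and LOX2 (-1.82) and aoc (-1.63) fell. Of 24 Aux/IAA genes 16 rose and 3 fell over all genes and adjusted over the list alone (adjusted p = 0.000279, or 0.565 with an estimated correlation), with IAA23 at 2.67 and IAA5 at -1.11. All 6 NAC genes rose by both counts, NAC45 by 3.15 (adjusted p = 0.000279, or 0.565 with an estimated correlation). Among 69 genes for calcium sensors and their kinases 35 rose and 18 fell, or 35 and 19 adjusted over the list alone (adjusted p = 0.000457, or 0.565 with an estimated correlation). CIPK14 rose by 3.54 and CML27 by 3.29. Of 54 PP2C genes 27 rose and 14 fell by both counts (adjusted p = 0.00249, or 0.565 with an estimated correlation), PP2C32 by 3.08 and PP2C78 by -2.50. The cold-associated regulators had 5 of 9 genes higher and 1 lower by both counts (adjusted p = 0.0245, or 0.565 with an estimated correlation), with MYB4 at 3.04 and LTI6A at -0.70. The list of trehalose, proline and inositol synthesis had 6 of 9 higher and 3 lower by both counts (adjusted p = 0.0459, or 0.565 with an estimated correlation), with TPP1 at 3.21. Without OE cold replicate 1 or 2 its adjusted p was 0.0502 and 0.0507. Of 6 WRKY genes 4 rose and 1 fell by both counts (adjusted p = 0.0478, or 0.565 with an estimated correlation), WRKY24 by 3.12, and leaving out the same arrays gave the same adjusted p of 0.0502 and 0.0507. Dimmer probe sets gave 1.43 and 2.83 for IAA23 and 1.27 for CML27. No list call in any comparison holds with an estimated correlation. The estimate was 0.02 for Aux/IAA and 0.03 for the cold-associated regulators, close to the preset 0.01. It was 0.07 to 0.37 for the other lists called in ZH11. So the loss of a call does not by itself show that the members of a list were correlated, and its cause was not tested.

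Lists tied to photosynthesis, water transport and chaperones fell for most members in ZH11 without passing as lists. Of 14 photosystem genes 9 fell and 2 rose (adjusted p = 0.127), as did 15 and 2 of 22 aquaporin genes (0.15), and 14 and 4 of 21 heat shock protein genes (0.127), HSP18.8 by -2.46. The clock list had 6 of 7 genes lower (0.0816), PRR73 by -2.40, while LHY rose by 3.17. Among 5 DREB1 genes 4 rose (0.0626), DREB1B by 2.59. Further lists that did not pass had these adjusted p-values and example changes. They were abscisic acid and SnRK2 (0.09; ABA8OX1 3.49, ZEP -2.72), heat shock factors (0.118), chitinases (0.153; NPR4 2.30), MAP kinases (0.157; MPK3 2.56), LEA and dehydrins (0.421; LIP9 2.43), ribosomal proteins (0.421, with 14 of 26 lower), sugar transporters (0.421) and type A response regulators (0.535, with 9 of 14 lower). Diterpenoid phytoalexins (0.647; CYP76M7 -3.29), cellulose synthase-like (0.659), class III peroxidases (0.659), reactive oxygen scavenging (0.659; AOX1 2.31, APX2 -2.02), vesicle transport (0.799), lignin (0.799; PAL06 2.75), chlorophyll synthesis (0.814; PORB -3.25), chlorophyll breakdown (0.814), BURP proteins (0.871; PMEI28 3.19, BURP2 -2.28) and cellulose and xylan synthesis (0.894) did not pass either. For cell cycle genes (0.647), starch and sucrose enzymes (0.659) and wall loosening (0.963) the test pointed up while the median and the mean were below 0. Camera sets a list against the other genes, so its direction can differ from the sign of the mean. Wall loosening had a median of -0.10 and a mean of -0.30. Dimmer probe sets gave 0.10 and 0.16 for LIP9 and -0.84 for BURP2.

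The overexpressing lines met the same chilling with largely the same genes. In OE, cold changed 18747 probe sets, 54.6% of those tested, with 7850 higher and 10897 lower (8784 and 10257 after quantile normalization). At 2-fold or more the counts were 2412 and 3167, and over genes 4050 rose and 6605 fell. JAZ9 had the largest rise among named genes, 5.84 ± 0.20 (adjusted p = 4.48e-09), to a mean signal of 2430. Its signals before cold lay near the array medians, as did those of HSF05, so the sizes of these rises depend on the pseudocount. DREB1B rose by 5.18 ± 0.14, from 109 to 4460 (adjusted p = 1.02e-09). SWEET2b rose by 4.63, GRXC15 by 4.55, the abscisic acid hydroxylase gene ABA8OX1 by 4.42, HSF05 by 4.30, CML31 by 4.12 and MYB4 by 4.10. The falls were -4.37 ± 0.09 for CIPK10 (adjusted p = 2.84e-10), -3.72 for LHCP, -3.45 for HOX4, -3.24 for CAB2R, -2.95 for TIP1-2, -2.94 for RCABP69, -2.87 for CKS1 and -2.76 for ADF-11. These calls were kept in each fit that left out 1 array.

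The called lists in OE were 10. Those up were jasmonate (19 higher and 5 lower of 26, adjusted p = 5.03e-05, or 0.594 with an estimated correlation), NAC (6 of 6, 0.000367, or 0.429 estimated), calcium sensors and their kinases (34 and 20 of 69, 0.00141, or 0.594 estimated), Aux/IAA (13 and 3 of 24, 0.00262, or 0.429 estimated) and PP2C (30 and 14 of 54, 0.00262, or 0.661 estimated). DREB1 (4 of 5, 0.00442, or 0.486 estimated), the cold-associated regulators (6 and 1 of 9, 0.0296, or 0.486 estimated) and trehalose, proline and inositol synthesis (6 and 2 of 9, 0.0324, or 0.661 estimated) were also up. Aquaporins were down, with 16 of 22 lower and 2 higher (0.00946, or 0.429 estimated), as was the clock list, with 6 of 7 lower (0.0466, or 0.661 estimated). Without ZH11 normal replicate 1 or OE normal replicate 1 the clock list had an adjusted p of 0.051 and 0.0576. Adjusted over the list alone, 5 DREB1 genes, 31 PP2C genes and 35 calcium genes rose, and 16 aquaporin genes fell. DREB1A rose by 3.91, WRKY24 by 3.72, PP2C32 by 3.66 and CML15 by 3.38, and PIP2-4 changed by -2.24. WRKY (0.0698) did not pass in OE.

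Across 15841 genes the cold changes in ZH11 and in OE had a Pearson correlation of 0.95, a description across genes that are not independent replicates. Both comparisons called 3538 genes higher, where 1041.8 would be shared by chance, and 6067 lower, where 2985 would be. Opposite calls were made for 11 genes that fell in ZH11 and 4 that rose, the unnamed LOC4328185, LOC4347061, LOC4335802 and LOC4341948, chosen after their values were seen. Among all 15, LOC4325228, which fell in ZH11 and was chosen in the same way, had the largest interaction, 1.37 (adjusted p = 0.00107), and LOC4328185 had -1.05 (adjusted p = 0.0114). Most of the 15 did not pass the interaction test. LOC4335802 had -0.54 (adjusted p = 0.0558), and CML5, which has a name, had 1.05 (adjusted p = 0.0898). The comparisons of OE with ZH11 before and after cold share no arrays but use the same 2 OE lines, so they are not independent. Their correlation across genes was 0.51. They shared 96 genes called higher against 17.2 by chance and 40 called lower against 5.7. Without OE normal replicate 2 that correlation was 0.37.

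**Figure D1:**
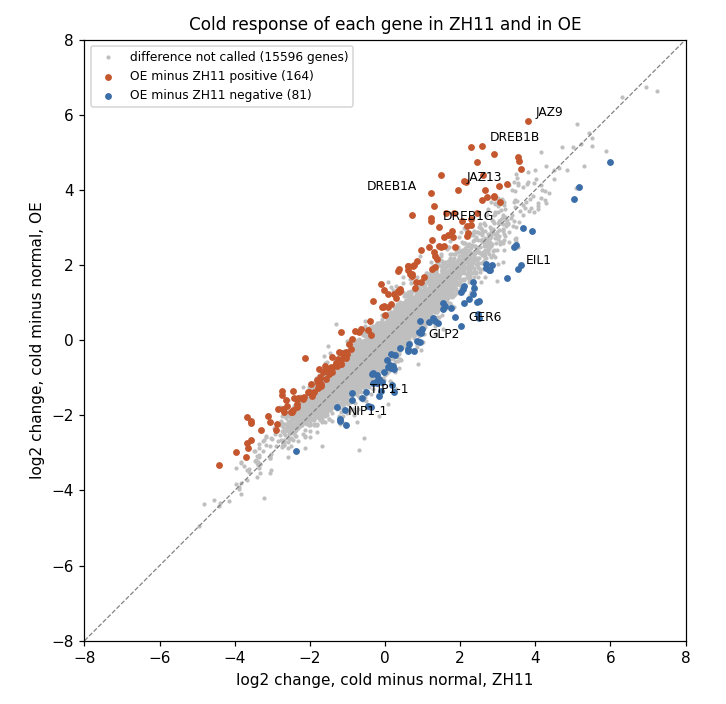
Log2 change with cold in ZH11 (x axis) and in OE (y axis) of 15841 genes, each a point, with the line of equal change dashed. Coloured points are the 164 genes with a positive and 81 genes with a negative called interaction, and DREB1A, DREB1B, DREB1G, JAZ9 and JAZ13 lie above the line.

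Before cold, overexpressing and wild-type seedlings were close to each other. Genes that passed included 3 chitinases, enzymes that degrade the walls of fungi. In this comparison 408 probe sets were called, 1.2% of those tested, with 265 higher in OE and 143 lower. At 2-fold or more there were 90 and 22, and over genes 151 and 87. The count depended on single arrays. It was 151 without ZH11 normal replicate 1, 163 without ZH11 normal replicate 2, 240 and 244 without ZH11 cold replicates 1 and 2, 835 without OE normal replicate 1 and 195 without OE normal replicate 2. Within the rule for named genes, the chitinase gene Cht2 was higher in OE by 1.58 ± 0.14 (mean signals 483 and 152, adjusted p = 0.000338). The ethylene signalling gene EIL1 was higher by 1.33 ± 0.11 (1050 and 405, adjusted p = 0.000228), Cht11 by 0.99 ± 0.07 (adjusted p = 7.05e-05), Cht6 by 0.92 ± 0.13 (adjusted p = 0.00747) and GH3-8 by 0.88 ± 0.16 (adjusted p = 0.0283). The gene listed as MS changed by -1.58 ± 0.25 (130 and 398, adjusted p = 0.0154), the diterpenoid gene CYP76M7 by -1.07 ± 0.11 (adjusted p = 0.00107), SAUR39 by -0.81 ± 0.11 (adjusted p = 0.00756), NAC45 by -0.68 ± 0.13 (adjusted p = 0.0406) and AOS by -0.59 ± 0.12 (adjusted p = 0.0458). Outside that rule, LOC4331398 and LOC4340325 were further apart, as given under other observations, and were chosen after their values were seen. Cht2, EIL1, Cht11 and CYP76M7 were called in each fit that left out 1 array. Without ZH11 normal replicate 1 the adjusted p was 0.0789 for Cht6, 0.127 for GH3-8, 0.132 for MS, 0.0833 for SAUR39, 0.279 for NAC45 and 0.363 for AOS. Without ZH11 normal replicate 2 it was 0.17 for GH3-8, 0.056 for MS and 0.0598 for AOS, and without OE normal replicate 2 it was 0.0681 for Cht6, 0.0958 for GH3-8, 0.0535 for SAUR39, 0.121 for NAC45 and 0.097 for AOS. Without OE normal replicate 1 it was 0.0971 for NAC45 and 0.113 for AOS, and without either ZH11 cold array GH3-8, NAC45 and AOS had 0.063 to 0.114. NAC45 also lost its call without either OE cold array (0.0571 and 0.0575).

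Of 16 genes in the list of chitinases and defence proteins, 3 were higher over all genes, and 9 were higher and 1 lower adjusted over the list alone (camera adjusted p = 3.53e-05, or 0.319 with an estimated correlation). Ribosomal proteins had 0 of 26 called by either count, with a median of 0.10 (adjusted p = 0.00013, or 0.844 estimated). Without ZH11 normal replicate 1 or OE normal replicate 1 that adjusted p was 0.103 and 0.399. Aux/IAA had 0 of 24 called over all genes and 5 lower adjusted over the list alone, with a median of -0.12 (adjusted p = 0.000157, or 0.319 estimated). NAC had 1 of 6 lower (0.00562, or 0.508 estimated), and 0.164 without OE normal replicate 1. The lists of cellulose and xylan synthesis (1 of 31 higher, UAM1 at 0.39, list direction down, 0.0311, or 0.642 estimated), lignin (0.0414, or 0.642), wall loosening (0.0414, or 0.508) and abscisic acid and SnRK2 (1 of 21 higher, SAPK2 at 0.29, 0.0428, or 0.849) each lost the call without some arrays. Their adjusted p without OE normal replicate 2 was 0.0663, 0.103, 0.906 and 0.312, and without ZH11 normal replicate 2 it was 0.0637, 0.163, 0.271 and 0.202. Without OE normal replicate 1 it was 0.175 for cellulose and xylan synthesis, 0.109 for lignin and 0.0711 for abscisic acid, and without ZH11 normal replicate 1 it was 0.062 for cellulose and xylan synthesis. The single calls lost their place in 5 fits for UAM1 (0.0562 to 0.175) and in 7 for SAPK2 (0.082 to 0.295). Lignin (23 genes) and wall loosening (29 genes) had 0 members called by either count. At an unadjusted p under 0.05 limma gave 4 lignin, 8 wall loosening, 7 ribosomal protein and 8 Aux/IAA genes, and 3179 probe sets in all.

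After cold the genotypes stood further apart. Cold regulators of the DREB1 family were higher in OE for 4 of 5 genes, while 9 of 24 Aux/IAA, 9 of 29 wall-loosening and 8 of 22 aquaporin genes were lower. Here 4487 probe sets were called, 13.1% of those tested, with 2790 higher in OE and 1697 lower. This balance depended on scaling, with 2374 and 2079 after quantile normalization and 3172 and 1488 after median centring. At 2-fold or more there were 223 and 150, and over genes 1804 and 1035. The count was 1131 without ZH11 cold replicate 1, 1382 without ZH11 cold replicate 2, 2011 without OE cold replicate 1 and 2213 without OE cold replicate 2. DREB1A was higher in OE by 2.64 ± 0.14 (mean signals 961 and 141, adjusted p = 9.46e-06), DREB1G by 2.51 ± 0.27 (939 and 148, adjusted p = 0.000452) and DREB1B by 2.07 ± 0.14 (4460 and 1050, adjusted p = 2.26e-05). DXPS was higher by 2.35 ± 0.15 (adjusted p = 1.92e-05) and JAZ13 by 2.34 ± 0.21 (adjusted p = 0.000152). The metallothionein gene MT1B changed by -1.97 ± 0.32 (931 and 3690, adjusted p = 0.00414), MS by -1.84 ± 0.25 (adjusted p = 0.00165) and the germin-like gene GER6 by -1.72 ± 0.14 (101 and 369, adjusted p = 7.86e-05). The expansin gene EXPA7 changed by -1.69 ± 0.39 (adjusted p = 0.0204) and LAC24 by -1.64 ± 0.44 (adjusted p = 0.0363). The other probe set of EXPA7, dimmer, gave -0.07. Without ZH11 cold replicate 1 the adjusted p was 0.0518 for MT1B, 0.0759 for EXPA7 and 0.252 for LAC24, whose change was then -0.92, and without ZH11 cold replicate 2 it was 0.139 for EXPA7. Without OE cold replicates 1 and 2 it was 0.08 and 0.0734 for EXPA7 and 0.128 and 0.109 for LAC24.

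Of 24 Aux/IAA genes, 9 were lower in OE after cold, or 12 adjusted over the list alone (adjusted p = 2.13e-05, or 0.199 with an estimated correlation), IAA31 by -1.13 and IAA14 by -0.90. The mean log2 signal of IAA14 was low (5.6), so the size of its change depends on the pseudocount. Wall loosening had 9 of 29 lower, or 10 lower and 1 higher adjusted over the list alone (0.00032, or 0.199 estimated). Aquaporins had 8 of 22 lower and 1 higher, or 10 and 2 adjusted over the list alone (0.00182, or 0.199 estimated), with TIP2-2 at -1.05, NIP1-1 at -0.93 and TIP1-2 at 0.84. DREB1 had 4 of 5 higher by both counts (0.00182, or 0.378 estimated). Cellulose and xylan synthesis had 6 of 31 lower and 2 higher, or 10 and 3 adjusted over the list alone (0.00404, or 0.505 estimated). Ribosomal proteins had 2 of 26 higher, RPS26 and RPS10 at 0.23 each, or 0 adjusted over the list alone (0.024, or 0.924 estimated), and 0.12 without ZH11 cold replicate 2 and 0.329 without OE cold replicate 2. Jasmonate was not called as a list (0.434), with 9 of 26 genes higher. Members of uncalled lists also passed, among them, with calls kept in each fit without 1 array, BIP1 (1.05), HSF07 (1.32), CML15 (1.27), ABA8OX1 (0.99), MYB4 (0.80), APX7 (0.82), CIN1 (0.87), WRKY76 (-1.24), SUS1 (-0.94) and INO1 (-0.61).

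The interaction asks directly whether the cold change differed between genotypes. The cold regulator genes DREB1A, DREB1B and DREB1G and the jasmonate repressor genes JAZ9 and JAZ13 rose further in OE. The ethylene signalling gene EIL1, the germin-like genes GER6 and GLP2, and 4 of 22 aquaporin genes differed the other way. There were 390 called probe sets, 1.1% of those tested, with 251 positive and 139 negative. Without OE normal replicate 1 there were 209 and 206, and without OE cold replicate 1 107 of the 230 then called were negative. At 2-fold or more there were 100 and 50, and over genes 164 and 81. The count was 69 without ZH11 cold replicate 1, 115 without ZH11 cold replicate 2, 118 and 211 without ZH11 normal replicates 1 and 2, and 230 without OE cold replicate 1. The log2 rise with cold was larger in OE by 2.69 ± 0.20 for DREB1A (adjusted p = 0.000576), 2.59 ± 0.19 for DREB1B (adjusted p = 0.000576), 2.27 ± 0.38 for DREB1G (adjusted p = 0.021), 2.06 ± 0.30 for JAZ13 (adjusted p = 0.0114) and 2.03 ± 0.28 for JAZ9 (adjusted p = 0.00924). EIL1 had -1.63 ± 0.15 (adjusted p = 0.00154). Its mean signal was 405 before and 4850 after cold in ZH11, and 1050 and 3930 in OE. GER6 had -1.61 ± 0.19 (adjusted p = 0.00454), GLP2 -1 ± 0.18 (adjusted p = 0.0312, and -1.63 for its other, dimmer probe set), NIP1-1 -0.93 ± 0.13 (adjusted p = 0.011) and TIP1-1 -0.91 ± 0.13 (adjusted p = 0.00905). DREB1A, DREB1B, EIL1 and GER6 were called in each fit that left out 1 array. Without ZH11 cold replicate 1 the adjusted p was 0.13 for DREB1G, 0.0837 for JAZ13, 0.0681 for JAZ9, 0.147 for GLP2, 0.0799 for NIP1-1 and 0.0614 for TIP1-1. Without ZH11 cold replicate 2 it was 0.0854 for DREB1G, 0.054 for JAZ13, 0.0601 for JAZ9, 0.148 for GLP2 and 0.0601 for NIP1-1. DREB1G also had 0.0606, 0.066 and 0.0547 without ZH11 normal, OE normal and OE cold replicate 1. GLP2 had 0.122 and 0.0982 without ZH11 normal replicates 1 and 2, 0.0646 without OE normal replicate 1 and 0.0773 without OE cold replicate 2.

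**Figure D2:**
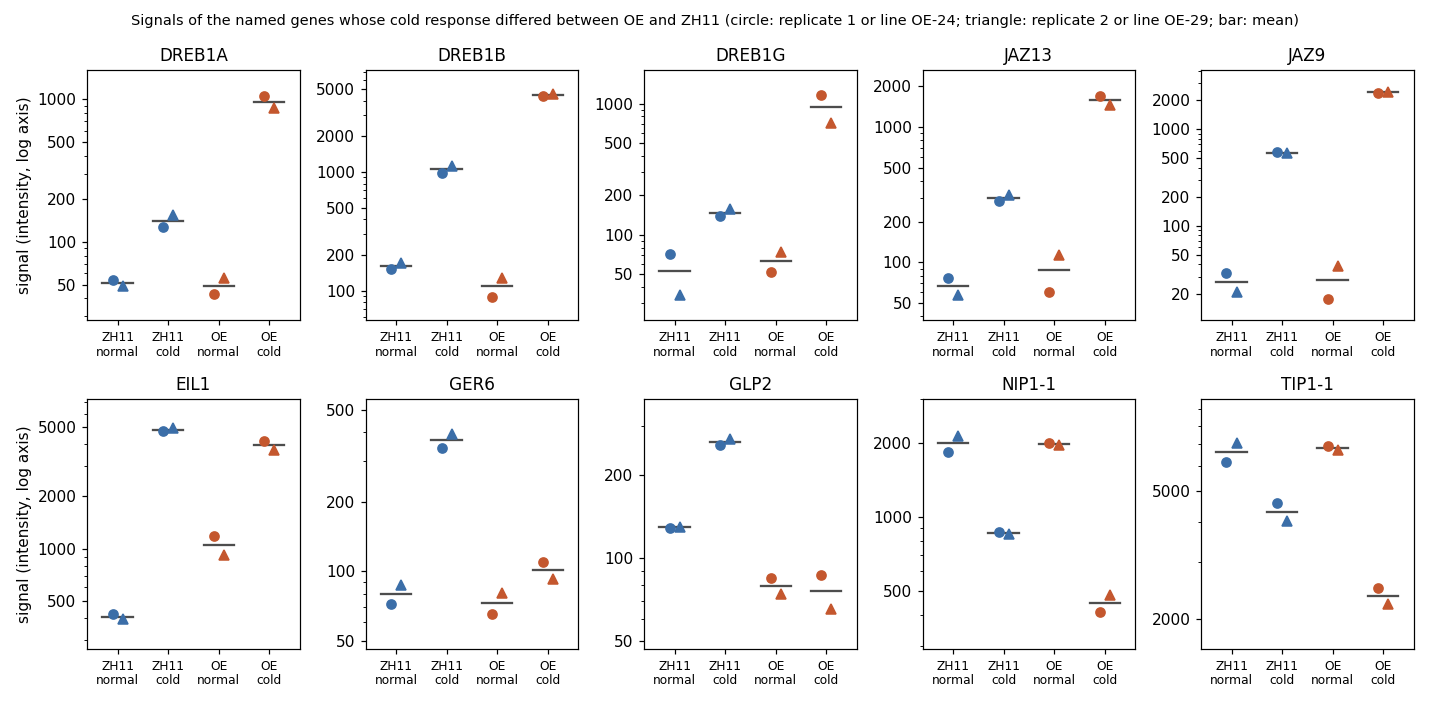
Signal (intensity, log axis) of 10 genes in each array of the 4 groups, with circles for replicate 1 or line OE-24, triangles for replicate 2 or line OE-29 and bars for means. After cold, both OE arrays lie above both ZH11 arrays for DREB1A, DREB1B, DREB1G, JAZ9 and JAZ13, and below them for the other 5 genes.

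Aquaporins differed as a list in the interaction, with 4 of 22 negative, or 8 negative and 1 positive adjusted over the list alone, and a median of -0.28 (adjusted p = 1.29e-05, or 0.184 with an estimated correlation). Beside NIP1-1 and TIP1-1 these were TIP2-2 (-0.89) and PIP1-1 (-0.57), which lie outside the rule for named genes and were chosen after their values were seen. DREB1 had 3 of 5 positive, or 4 adjusted over the list alone, with a median of 2.27 (9.49e-05, or 0.405 estimated). Aux/IAA had 0 of 24 called over all genes and 1 negative adjusted over the list alone, with a median of -0.10 (0.0156, or 0.41 estimated). Wall loosening had 0 of 29 called and 1 negative adjusted over the list alone, with a median of -0.11 (0.0163, or 0.41 estimated). At an unadjusted p under 0.05 limma gave 5 Aux/IAA and 4 wall loosening genes, and 4781 probe sets in all. Without ZH11 normal replicate 1 or OE normal replicate 1 the adjusted p was 0.123 and 0.133 for Aux/IAA and 0.119 and 0.449 for wall loosening, and without OE cold replicate 1 it was 0.0804 for Aux/IAA. Jasmonate was not called as a list (0.526), with 3 of 26 genes positive. Among other lists CML15 (1.53), HSF07 (1.26), MYB4 (1.05) and BIP1 (0.93) were positive. The call of CML15 and that of BIP1 held without each array, that of MYB4 was lost once (0.0605), and that of HSF07 was lost in 3 fits (0.0519 to 0.0847).

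Over both treatments together, 8 of 16 chitinase and defence genes were higher in OE and 1 lower, and 9 of 24 Aux/IAA genes, which take part in auxin response, were lower. The 3431 called probe sets were 2012 higher and 1419 lower, with 102 and 39 at 2-fold or more, and over genes 1306 and 924. The OE arrays came from 2 lines, each used in both treatments, and the model took these arrays as independent. The count was 2013 and 2058 without ZH11 normal replicates 1 and 2, 1570 and 1654 without ZH11 cold replicates 1 and 2, and 5912 without OE normal replicate 1. DXPS was higher by 1.47 ± 0.11 (adjusted p = 3.59e-05), Cht2 by 1.34 ± 0.10 (adjusted p = 4.43e-05), Cht6 by 1.12, Cht11 by 0.94 and the ammonium transporter gene AMT3-3 by 0.92. MS changed by -1.71 ± 0.18 (adjusted p = 0.00042), MT1B by -1.63, GLP2 by -1.11 (-1.69 for its other probe set), a peroxidase gene by -1.03 and IAA31 by -0.92. Each of these was called without each array in turn. The called lists were Aux/IAA (9 of 24 lower, or 12 adjusted over the list alone, 5.57e-06, or 0.31 with an estimated correlation), wall loosening (6 of 29 lower and 1 higher, or 13 and 1, 0.000397, or 0.31), ribosomal proteins (3 of 26 higher, or 12, 0.00103, or 0.67) and cellulose and xylan synthesis (6 of 31 lower and 3 higher, or 10 and 4, 0.00152, or 0.352). DREB1 (3 of 5 higher, or 4, 0.00556, or 0.352) and chitinases (8 of 16 higher and 1 lower, or 8 and 2, 0.00636, or 0.352) were called as well. No DREB1 gene was called higher in OE before cold, with 0 of 5 called over all genes and 1 lower adjusted over the list alone. The values before cold were -0.05 for DREB1A, -0.52 for DREB1B and 0.24 for DREB1G. The DXPS value averages 0.58 before cold and 2.35 after. Without OE normal replicate 1 the adjusted p was 0.0815 for ribosomal proteins and 0.0638 for chitinases.

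Some markers of other tissues changed with cold. Of 6 root genes, 1 rose and 3 fell in ZH11, NAS2 by 1.18, NAS3 by -1.89, IRT1 by -1.13 and NRAMP5 by -1, and 2 rose and 4 fell in OE and over both genotypes. Of 4 seed storage genes 1 rose and 1 fell in each cold comparison, RAG2 by 0.38 and GLUA-2 by -0.48 in ZH11 (-0.05 and 0 for their other, dimmer probe sets), where RAG2 had an adjusted p of 0.0645 without ZH11 cold replicate 1 and 0.0985 without ZH11 normal replicate 2. Of 8 flower and meiosis genes, MADS2 fell in ZH11 by -0.30, with an adjusted p of 0.0508 to 0.161 in 4 fits without 1 array. NRAMP5 in ZH11 was chosen after its values were seen. The mean log2 signals of NAS2, IRT1 and RAG2 were low (6.02, 5.94 and 5.71), so the sizes of their changes depend on the pseudocount. Seed storage (4 genes tested) and flower and meiosis genes (8 tested) had 0 members called in limma in the 3 comparisons of OE with ZH11 and the interaction, with 0 at an unadjusted p under 0.05 as well. Their lists had adjusted p-values of 0.814 and 0.996 with cold in ZH11, where the tests pointed up against a mean of -0.02 and -0.11. Between genotypes 1 root gene differed, NRAMP5, by -0.61 after cold (adjusted p = 0.0169, with 0.0578 to 0.124 in 4 fits without 1 array) and by -0.53 over both treatments. Adjusted over the list alone 3 root genes were higher after cold and 1 lower, and over both treatments 2 were higher and 1 lower. The root list had an adjusted p of 0.814 with cold in ZH11. Meristem homeobox genes had fewer than 3 tested members. Averaged over genotypes, cold changed 23446 probe sets, 10659 higher and 12787 lower (11794 and 11932 after quantile normalization), with 2406 and 3415 at 2-fold or more. SWEET2b (4.96) and JAZ9 (4.82) rose most among named genes and CIPK10 (-4.59) fell most. The 7 called lists were Aux/IAA, calcium sensors and their kinases, the cold-associated regulators, DREB1, jasmonate, NAC and PP2C, jasmonate with an adjusted p of 0.000163 (0.593 estimated).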

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

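The tests on the OE lines, on scaling, on clock genes and on transformed controls were chosen, and their bounds set, only after the results were seen, while the other splits of the arrays were planned.

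The cold change differed between OE and ZH11 by the interaction test in limma for 21 genes that the naming rule covers. The 5 largest differences in each direction (OE minus ZH11, log2) were 2.69 for DREB1A, 2.59 for DREB1B, 2.27 for DREB1G, 2.06 for JAZ13 and 2.03 for JAZ9, and -1.63 for EIL1, -1.61 for GER6, -1 for GLP2 (-1.63 for its other probe set), -0.93 for NIP1-1 and -0.91 for TIP1-1. The others, named as list members, were 1.53 for CML15, 1.26 for HSF07, 1.05 for MYB4, 0.93 for BIP1, 0.91 for CYP76M7, 0.61 for HSP18.8 and 0.58 for CML10, and -0.82 for SUS1, -0.74 for SWEET1b, -0.72 for PP2C48 and -0.67 for INO1. Camera also called 4 lists in the interaction, with medians of 2.27 for DREB1 factors, -0.28 for aquaporins, -0.11 for wall loosening and -0.10 for Aux/IAA, and called 0 of them with an estimated correlation. DREB1A, DREB1B, EIL1, GER6, CML15 and BIP1 kept their calls without each array in turn, and the other 15 genes lost theirs in at least 1 such fit.

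Splits of the 8 arrays into 4 and 4, the real split among them, were fitted with the remaining factor in the model. This was done in 34 of 35 cases, since the split equal to that factor could not be fitted. These models hold no interaction term, so their counts differ from those of the group-means model. For OE against ZH11 the real split gave 1591 probe sets and the highest other split 26, so only the real split, 1 of 34, reached that count. For cold the real split gave 22911 and the highest other 0, again 1 of 34. These shares do not exclude chance for either count, because they take the 8 arrays as exchangeable. Treatment separated the arrays on a component with 87.3% of the variance, and each OE line was used in both treatments. The other splits also leave the real factor in the spread, which lowers their counts.

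DREB1A, DREB1B, DREB1G, JAZ9, JAZ10 and JAZ13 rose further with cold in OE, and JAZ10 was named after its values were seen. For a difference from a single line, list members were picked in 1 line and 1 ZH11 replicate. They were read in the other line and the other ZH11 replicate. Members of the DREB1 and jasmonate lists picked at 1 log2 or more had medians of 1.34 to 2.80 in the line not used to pick them. JAZ5, which was not called, rose further in OE-24 alone. These lists were taken up because members had been called over both lines, so the test could hardly fail and does not decide the question. The called genes named above were picked by their calls over both lines, so a rise in each line was likely in advance. They rose further by 0.94 to 2.96 in OE-24 and 0.80 to 2.42 in OE-29. Differences in scale between arrays were too small to account for rises of this size, since array medians ran only from 27.2 to 28.2. The median interaction was 2.07 with quantile normalization and 2.17 without, a test that arrays so alike in scale could hardly fail. Another hour of the day at sampling of OE after cold stays open, because 3 of 7 clock genes differed between genotypes after cold (LHY -0.45, PRR37 0.44, PRR73 0.27), fewer than the bound for that explanation but more than the bound against it. That count rests on single arrays. Without ZH11 cold replicate 1 the adjusted p for LHY, PRR37 and PRR73 was 0.184, 0.0808 and 0.228, without ZH11 cold replicate 2 it was 0.119, 0.0723 and 0.124, and without OE cold replicate 1 it was 0.0985, 0.0742 and 0.234. LHY also had 0.118 without OE cold replicate 2, and PRR73 had 0.0606 and 0.0604 without ZH11 normal replicates 1 and 2. An effect of transformation and culture of the lines stays open as well, because no array came from transformed plants without the transgene. The biological explanation that the design gives, an effect of OsTMF overexpression on the cold response, remains a hypothesis.

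Chitinase and defence signals were higher in OE over both treatments for 8 of 16 genes. As a list they were called before cold and over both treatments, but were not among the 6 lists called after cold. By the same kind of test, list members picked at 0.5 log2 or more had medians of 0.75 to 1 in the line not used to pick them. This list too was taken up because of its calls over both lines, so the test does not decide on a single line as the source. The called genes were higher in each line, by 0.27 to 1.23 in OE-24 and 0.49 to 1.46 in OE-29. Since they were picked by calls over both lines, this was likely in advance. An effect of transformation and culture of the lines cannot be told apart from an effect of the transgene, because 0 of the 8 arrays came from transformed plants without it. Overexpression of OsTMF stays among the open explanations.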

How the results depend on the processing

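All alternatives were planned, and none was chosen after the result was seen. In fits without an array, the lone array of its group is assumed to vary like the other groups. The floor for a log2 table was not run because the values are linear.

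Requiring 2-fold cut the counts by construction to 6267 (cold in ZH11), 5579 (cold in OE), 112 (OE against ZH11 before cold), 373 (after cold), 150 (interaction), 141 (OE over both treatments) and 5821 (cold over both genotypes). An adjusted p under 0.01 gave 148, 1543, 95 and 1340 for OE before cold, OE after cold, the interaction and OE over both treatments. With only its 4 arrays, OE before cold gave 226, from fewer samples. Without single arrays the counts ran from 151 to 835 for OE before cold, 1131 to 6352 after cold, 69 to 473 for the interaction and 1570 to 5912 over both treatments, while cold counts stayed within 1.5 times. The cause was not tested. Pseudocounts, scaling, the filter, the trend and the replicate blocks kept every count of probe sets within 1.5 times, but the balance of directions moved. With quantile normalization cold gave 10239 higher and 10756 lower in ZH11, against 9021 and 11647, and 11794 and 11932 over both genotypes, against 10659 and 12787. OE over both treatments had 1889 higher and 1662 lower with quantile normalization, against 2012 and 1419. After cold it had 2374 and 2079 with quantile normalization and 3172 and 1488 with median centring, against 2790 and 1697. With the replicate as a block over all arrays OE before cold gave 393 and the interaction 318, and with a block within genotype the interaction gave 382, of which 308 were shared with the 390. No scaling moved the median of all tested probe sets by over 0.1.

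Camera with an estimated correlation called 0 lists in each of the 7 comparisons, against 8 and 10 for cold in ZH11 and OE, 8, 6 and 6 for OE before cold, after cold and over both, 4 for the interaction and 7 for cold over both genotypes. With cold in OE, aquaporins lost the call at an estimate of -0.02, below the preset 0.01, so a higher correlation does not account for that loss. Fry, which does not compare a list with other genes, called 30, 30 and 33 lists for cold in ZH11, in OE and over both, and 2 each for OE before cold and the interaction. OE before cold had 5 lists with quantile normalization, 5 without the filter, and 3 to 10 without single arrays. The interaction had 2 to 4 without single arrays, and cold over both genotypes had 11 with the filter at the 60th percentile. With fry, flower and meiosis genes (adjusted p = 0.022) and wall loosening (0.00852) pointed down with cold in ZH11, opposite to camera. The means of these lists were -0.11 and -0.30. Camera sets a list against the other genes, and of all genes tested 7159 fell and 4075 rose, so the tests ask different questions. The cause of the other changes was not tested.

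The correlation of cold responses ran from 0.94 to 0.95 without single arrays, and that of the genotype differences from 0.37 to 0.52, lowest without OE normal replicate 2. Of 621 pairs of a named gene and a comparison, 479 kept their call without each array, 142 lost it at least once, and 0 reversed in any alternative. These genes were chosen by their calls in the main fit, so reversals were unlikely in advance. A pseudocount of 1 kept all 621 and quantile normalization 607. The highest numbers of losses for single arrays were 115 and 111, without ZH11 cold replicates 1 and 2. Genes below the 40th percentile were not tested, so changes near background are not covered.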

Other observations

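The test of the spread between arrays of a group was chosen only after the result was seen, as were the probe sets named here.

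In both treatments 10 probe sets differed at least 4-fold between lines OE-24 and OE-29 in the same direction, 7 higher in OE-24 and 3 in OE-29. Probe sets as far apart in both treatments but in opposite directions numbered 0 (two-sided binomial p = 0.00195, taking probe sets as independent), while the spread between arrays of a group ties no direction to a line, so it is not a sufficient account of these line differences. The largest was LOC4344283, with signals of 9881.1 and 11183.4 in OE-24, 76.4 and 130.4 in OE-29, and 16.7 to 74.6 in ZH11. The neighbouring numbers LOC4345609 and LOC4345610 differed in directions opposite to each other, with 5.7 against 91.5 and 179.7 against 29 in OE-24 and OE-29 before cold. BURP16 (LOC4348595) had 108.1 and 349.5 in OE-29, 8 and 9.3 in OE-24, and 12.5 to 84.1 in ZH11. Whether the insertion of the transgene or variation between plants lies behind them was not tested.

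Both probe sets of LOC4331398, which had no other name, had signals of 3.6 to 7.4 in ZH11 and 830.3 to 1838.2 in OE. LOC4340325 had signals of 6.8 to 16.4 in ZH11, and in OE 558.9 and 598.2 before cold and 208.4 and 211.8 after. The ZH11 signals lie below the array medians, so log2 differences would be set by the pseudocount and are not given. None of these was identified as OsTMF.

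The cold changes of all tested probe sets had a standard deviation in OE of 0.959 times that in ZH11, and a slope of 0.91 on those in ZH11. The slopes of lines OE-24 and OE-29 were 0.918 and 0.902.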
